A study of Homo sapiens with 6 samples.

How the data were processed

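RNA of native HEK293 cells and of 1 HEK293 clone transfected with CD44s was measured on 6 Affymetrix human genome U133 Plus arrays, 3 per group. Groups and replicate numbers were taken from the sample titles. The template of the transfected gene, its codon optimisation, the vector and the choice of the clone are as given per the labels. The values are log2 expression as the authors deposited them, with 1 value per probe set and array, and the log2 unit was checked against their range of 2.67 to 15.13. Partek is named in the submitters' processing notes without a version. The background correction, normalization and summarisation behind these values are not given in the sources used here, and neither are scan dates or batches. Medians of the 6 arrays lay between 5.17 and 5.22. Detection calls and scanner intensities were not used here, so no probe set was called present or absent, and the number of arrays limits the precision.

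Of 54675 probe sets, 62 Affymetrix controls were left out and 54613 were tested. The platform annotation gave 1 gene symbol for 41091 of these, several for 1801 and none for 11721. Symbols were updated through the gene identifier with a RefSeq table of assembly GRCh38.p14, which served only for names, chromosomes and order along them. As the deposited values name no genome build, no coordinates are given. A gene was represented by the probe set with the highest mean over all 6 arrays among those with that symbol alone, which gave 19775 genes. Of 994 genes written into the lists, 907 were measured.

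Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates, all 6 arrays). Adjusted p-values follow Benjamini and Hochberg, over all probe sets or over all genes, with a threshold of 0.05. Differences are log2 values, CD44s minus native, and a fold is the power of 2 of the difference. The 33 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry beside it. The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made later. The rule took the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold, with no overlap of the groups and with the higher group above the median of all probe sets, placeholder symbols left out. It also took CD44 and the hyaluronan synthases, and in each list up to 2 genes with the largest rise and up to 2 with the largest fall. It named 144 genes that are given, 94 of which had more than 1 probe set and 5 of which had called probe sets in both directions. The value given for a gene is that of its representative probe set, and its other probe sets may differ in size or not pass the threshold. In addition, 1 gene that the rule took is not reported here.

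The steps were tested on simulated values before use. With 200 of 54613 probe sets changed in simulated arrays of the same layout, 18 of 50 changes of 0.5 log2 units and 50 of 50 at each of 1, 2 and 4 log2 units were recovered, with 2 false calls. With no list shifted, camera called 0 lists over the 19775 genes. The simulated values were drawn independently for each probe set, so they do not show how camera behaves when genes are correlated. Far more probe sets were called in the real comparison (46.1%), so the recovered shares do not describe it.

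Alternatives were quantile normalization, centring each array on its median, leaving out the 40% dimmest probe sets, a trended and robust variance, array weights, the replicate number as a block, leaving out each array in turn, an unmoderated equal-variance test, a threshold of 0.01, the mean of all probe sets of a gene, and the other set tests. Cyclic loess between arrays was added after seeing the data.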

Results

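Gene expression was measured in HEK293 cells, a human embryonic kidney line, that carried a transfected CD44s gene and in native HEK293 cells. CD44s is the standard form of CD44, a cell surface receptor for hyaluronan. The CD44s cells came from 1 clone, picked for profiling because, in the labels' terms, its level of HA was average, and the transfected coding sequence was codon optimised. Each group had 3 arrays, given in the design as biological replicates, and no array of cells carrying an empty vector was analysed here. The arrays of a group were close to each other, with Pearson's r across 54613 probe sets of 0.996 to 0.997 among native arrays and 0.995 to 0.996 among CD44s arrays. Between the groups r lay from 0.925 to 0.927. The first principal component, which parted the groups, held 92.9% of the variance.

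The comparison of the groups asks which genes are expressed at another level in the CD44s clone than in native cells. The difference was broad. Of 19775 genes, 5863 were higher and 5439 were lower in the CD44s cells, which together is 57.2% of the genes (limma, adjusted p under 0.05). By at least 1 log2 unit, 1455 genes rose and 2149 fell, and by at least 4 log2 units 140 rose and 181 fell. Genes that were dim in native cells (mean under 5.26, the median of all probe sets) and bright in CD44s cells (mean over 9) numbered 66, and 89 genes showed the opposite. At the level of probe sets, 13314 rose and 11861 fell, of which 2853 and 4359 by at least 1 log2 unit. Genes of some chromosomes moved together, with a median of -0.84 relative to all genes for chromosome 18 and 0.30 for chromosome 8, over genes above the median of all probe sets. The median SD of a probe set was 0.108 among native and 0.120 among CD44s arrays. Higher calls made up 52.9% of called probe sets as deposited, but 49.0% after each array was centred on its median and 46.4% after cyclic loess. With 1 clone and no cells carrying an empty vector, the effect of CD44s was not separated from that of the clone or of the transfection. Nor was it separated from that of another cell line under one of the labels, or of a batch or handling difference between the groups. The p-values cover only the spread between these arrays.

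CD44 itself was far higher in the transfected cells. Of its 13 probe sets, 10 rose, 0 fell and 3 did not pass the threshold (limma). The 7 that rose by at least 5 log2 units did so by 5.15 to 6.08, from native means of 4.81 to 6.74 to CD44s means of 10.64 to 12.63. The brightest went from 6.74 ± 0.0728 to 12.63 ± 0.0689 (SD, n = 3 arrays each), a difference of 5.90 ± 0.0876 (SE, limma adjusted p = 6.03e-11 over all probe sets). The probe set designed on the sequence that the labels give as the template of the transfected gene rose by 5.92 ± 0.123 (SE). Which probes match the codon-optimised sequence was not analysed here, so these values do not separate transcripts of the transfected gene from those of the cells' own gene. The hyaluronan synthases HAS2 and HAS3, which make the polymer that CD44 binds, were also higher. HAS2 rose by 3.64 ± 0.188 (SE, limma adjusted p = 9.18e-08), from 4.57 ± 0.366 to 8.21 ± 0.272 (SD, n = 3). HAS3 rose by 3.47 ± 0.113 (SE, limma adjusted p = 3.26e-09), from 6.41 ± 0.159 to 9.88 ± 0.146 (SD, n = 3). HAS1 was not analysed here.

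**Figure D1:**
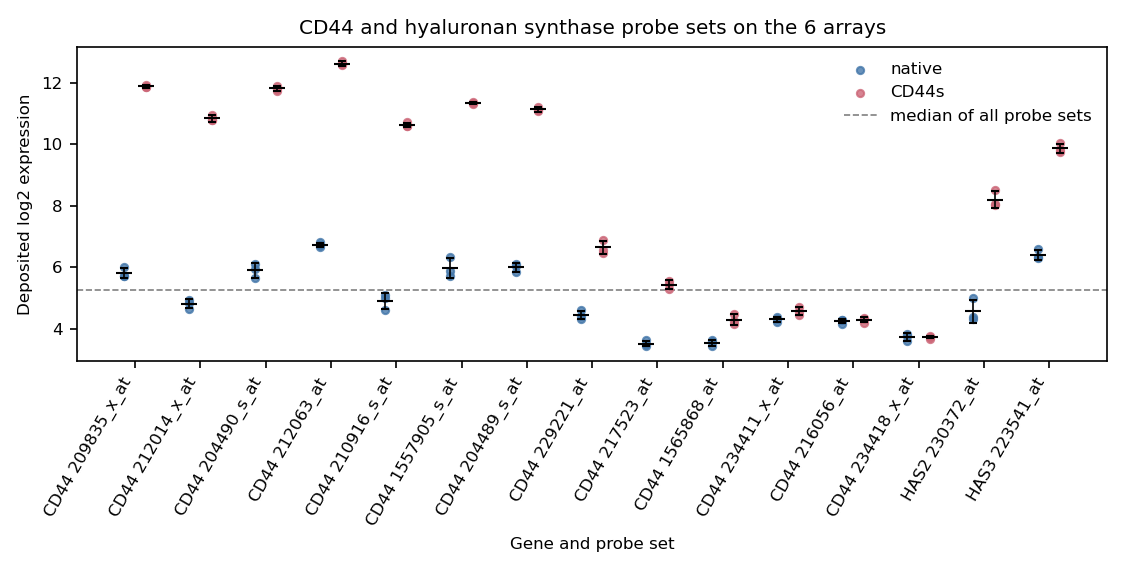
Deposited log2 expression (vertical axis) on each of the 6 arrays for the 13 CD44 probe sets and the probe sets that represent HAS2 and HAS3, with native arrays in blue, CD44s arrays in red, and black bars for the mean and SD of 3 arrays. The 7 CD44 probe sets at the left had native means of 4.81 to 6.74 and CD44s means of 10.64 to 12.63, and the dashed line marks 5.26, the median of all probe sets.

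The largest rises were in genes for secreted, membrane and cytosolic proteins that lay below the median of all probe sets in native cells. SRGN, which encodes the proteoglycan serglycin, rose from 3.95 ± 0.0994 to 13.92 ± 0.0746 (SD, n = 3), a difference of 9.96 ± 0.0918 (SE). The membrane protein gene TM4SF1 rose by 9.16, the gene of the calcium-binding protein S100A6 by 9.03 and that of the receptor tyrosine kinase AXL by 8.77. THBS1, encoding the matricellular protein thrombospondin, rose by 8.23 and PLAC8 by 7.74. The protein-crosslinking enzyme gene TGM2 (7.66), the myoferlin gene MYOF (7.56), the ERBB ligand gene NRG1 (7.48) and the nicotinamide methyltransferase gene NNMT (7.34) followed. Limma adjusted p over these genes ran from 4.83e-12 for SRGN to 2.26e-10 for NNMT. Signal over background is not known here, so the size of a change is not exact where either level is dim.

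The genes with the largest falls were bright in native cells and near the low end in CD44s cells. IRS4, an insulin receptor substrate, went from 13.89 ± 0.0287 to 4.58 ± 0.0935 (SD, n = 3) and fell by 9.31 ± 0.0872 (SE). The log2 difference was -8.84 for the peroxiredoxin gene PRDX2, -8.46 for ID4, an inhibitor of basic helix-loop-helix factors, and -8.21 for the adhesion molecule gene CADM1. It was -7.93 for PSAT1, an enzyme of serine synthesis, -7.67 for the integrin-binding protein gene EDIL3 and -7.16 for LIN28B, an inhibitor of let-7 maturation. AUTS2 (-7.15) and the gap junction gene GJA1 (-7.12) also fell. Limma adjusted p was at most 2.17e-10 for these genes, the highest being that of ID4. Here too other probe sets could differ: CADM1 had 6, from -8.21 to 0.22, and 3 of them fell past the threshold.

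**Figure D2:**
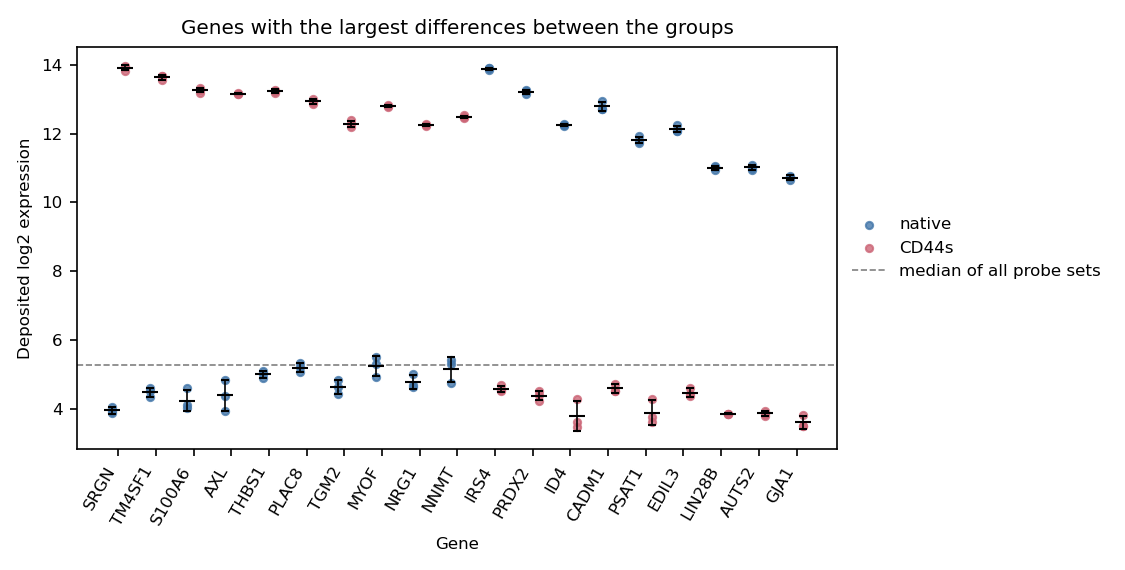
Deposited log2 expression (vertical axis) on each array for the genes with the largest rises (left) and falls (right), with native arrays in blue, CD44s arrays in red, and black bars for the mean and SD of 3 arrays. SRGN, at the far left, had means of 3.95 and 13.92 in native and CD44s cells, and IRS4, the first of the falling genes, 13.89 and 4.58; the dashed line marks 5.26, the median of all probe sets.

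Among 33 gene lists, 6 stood higher than the other genes and 2 lower (camera with a preset correlation of 0.01, adjusted over the lists), and with an estimated correlation 0 passed, the lowest adjusted p being 0.152. The list with the lowest p held interferon-stimulated genes, of which 25 of the 36 measured rose and 2 fell (25 and 2 adjusted over the list alone, 15 and 0 by at least 1 log2 unit). The immunoproteasome gene PSMB8 rose by 5.77 and BST2, which tethers virions, by 4.61, while the transcription factor gene IRF7 (-0.85) and the class I antigen gene HLA-B (-0.67) fell. Its adjusted p was 8.48e-06, and adjusted p = 0.234 with an estimated correlation. In the list of focal adhesion and actin genes, 22 of the 28 measured rose and 3 fell (23 and 3 adjusted over the list alone, 13 and 2 by at least 1 log2 unit), among them the tropomyosin gene TPM2 (5.50) and the myosin light chain gene MYL9 (4.39). TES (-3.02) and ENAH (-1.97), both of actin-linked adhesion proteins, fell. Camera gave adjusted p = 3.07e-05, and adjusted p = 0.152 with an estimated correlation. Among immediate-early and MAPK feedback genes, 22 of the 34 measured rose and 5 fell (23 and 5 adjusted over the list alone, 17 and 4 by at least 1 log2 unit), with rises of 6.31 for the AP-1 component gene FOSL1 and 5.06 for PHLDA1, and falls of ATF3 (-1.89) and SPRY1 (-1.61). The adjusted p was 0.000476, and adjusted p = 0.152 with an estimated correlation.

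Stress, cytokine and glycolysis genes were also higher as lists. For heat shock proteins and metallothioneins, 14 of the 23 measured rose and 3 fell (14 and 4 adjusted over the list alone, 11 and 1 by at least 1 log2 unit). The metallothionein gene MT1E rose by 6.06 and the quinone reductase gene NQO1 by 4.35, while DNAJA1 (-0.60) fell and HSPB8 fell 3.99-fold on the probe set that represents it and rose on the other. The list had adjusted p = 0.00171, and adjusted p = 0.164 with an estimated correlation. Of the NF-kappaB and cytokine list, 21 of the 29 measured rose and 5 fell (21 and 5 adjusted over the list alone, 13 and 2 by at least 1 log2 unit): the chemokine genes CXCL1 (3.27) and CXCL2 (2.86) rose, and the chemokine gene CXCL12 (-2.29) and SOD2 (-1.57), a mitochondrial superoxide dismutase, fell. Here adjusted p was 0.00223, and adjusted p = 0.234 with an estimated correlation. In glycolysis and the hypoxia response, 21 of the 33 measured rose and 5 fell (21 and 5 adjusted over the list alone, 11 and 2 by at least 1 log2 unit). PFKFB4, a regulator of glycolytic flux, rose by 2.56 and ANKRD37 by 2.42, and the pyruvate dehydrogenase kinase gene PDK3 (-3.52) and the oxygen-sensing hydroxylase gene EGLN3 (-1.19) fell. This list had adjusted p = 0.00226, and adjusted p = 0.234 with an estimated correlation.

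The lists that stood lower were TGF-beta and BMP response genes and oxidative phosphorylation. In the first, 10 of the 30 measured rose and 17 fell (10 and 17 adjusted over the list alone, 5 and 16 by at least 1 log2 unit), with a median log2 difference of -1.20. Besides ID4, the inhibitory SMAD gene SMAD7 fell by 4.41, whereas the ligand gene TGFB2 rose by 3.98 and CCN2, a matricellular protein gene, by 3.07. Its adjusted p was 0.0401 with the preset correlation, and adjusted p = 0.234 with an estimated correlation. The call also ended after centring each array (0.0536), after leaving out dim probe sets (0.108) and without native replicate 2 (0.0504). In oxidative phosphorylation, 3 of the 34 measured rose and 17 fell (3 and 17 adjusted over the list alone, 0 and 2 by at least 1 log2 unit). COX6B1 (-1.20) and NDUFA5 (-1.15), subunits of respiratory complexes, fell most, and UQCRC1 (0.51) and CYC1 (0.41) rose. Camera gave adjusted p = 0.0106, and adjusted p = 0.244 with an estimated correlation, and the call ended after leaving out dim probe sets (0.0658) and after cyclic loess (0.0910). Of the 33 lists 30 passed with fry, which asks only whether a list's genes move one way on balance.

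**Figure D3:**
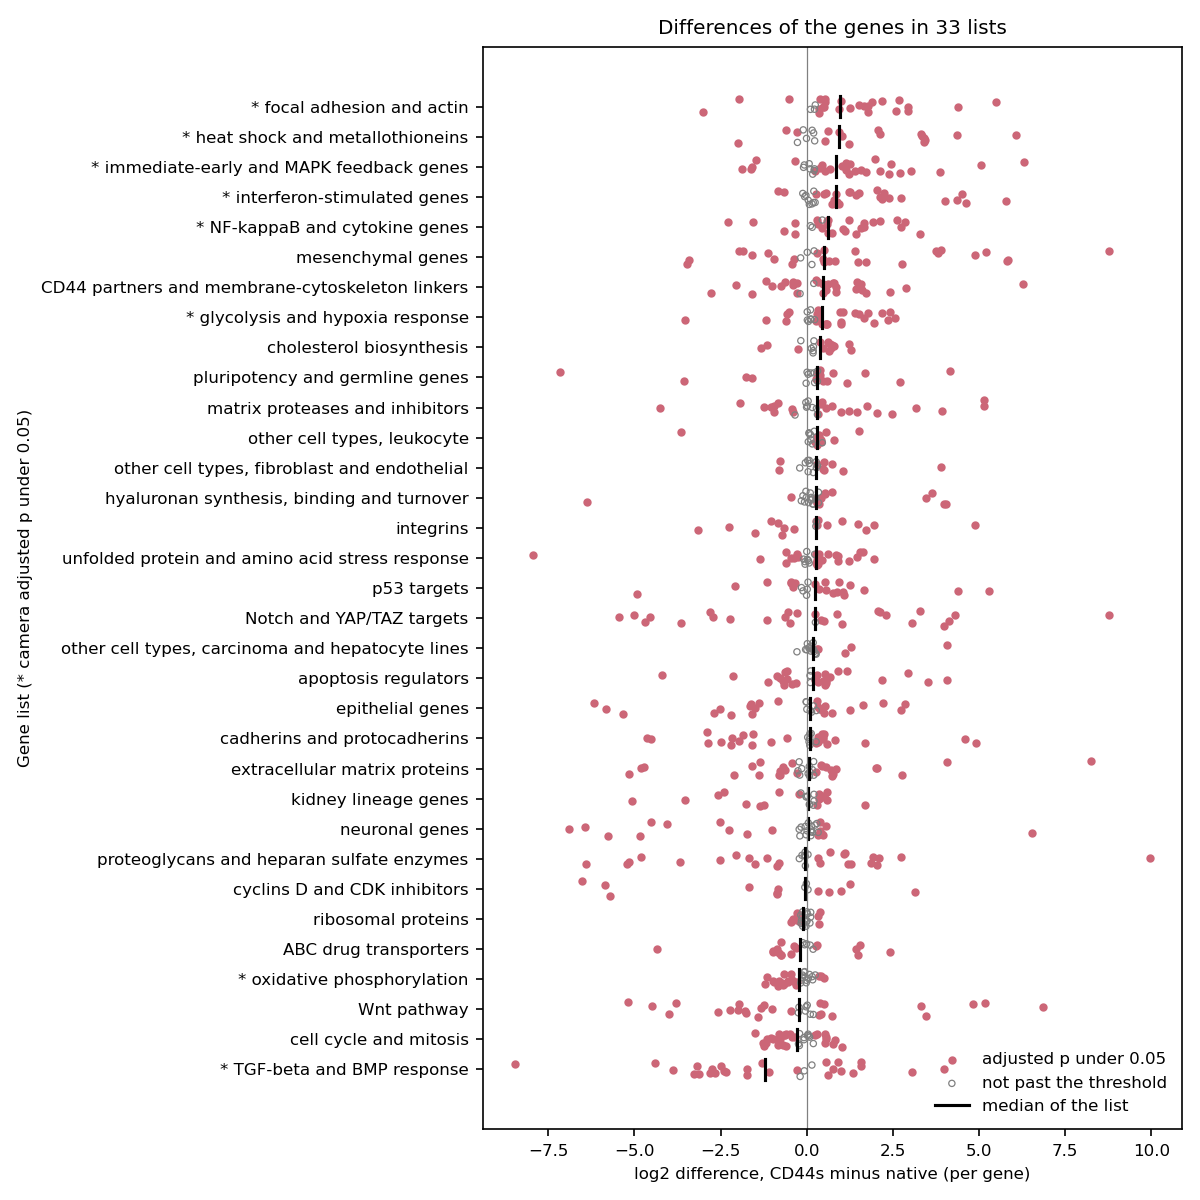
Log2 difference, CD44s minus native (horizontal axis), of each measured gene in 33 lists (vertical axis), with filled points for genes with limma adjusted p under 0.05, open points for the others and black bars for list medians. Stars mark the 8 lists with camera adjusted p under 0.05, and within most lists genes lay on both sides of 0.

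The genes closest to the transfected receptor moved in both directions. For hyaluronan synthesis, binding and turnover, 12 of the 29 measured rose and 2 fell (10 and 2 adjusted over the list alone, 4 and 1 by at least 1 log2 unit), and camera did not call the list (adjusted p = 0.0714). Besides HAS2 and HAS3, the hyaluronan receptor gene LAYN rose by 4.04 and PTX3, whose product binds hyaluronan-rich matrix, by 3.97. The hyaluronan-binding proteoglycan gene VCAN fell by 6.37, from 11.27 ± 0.214 to 4.90 ± 0.221 (SD, n = 3), and the link protein gene HAPLN3 (-0.44) also fell. Of CD44 partners and membrane linkers, 18 of the 31 measured rose and 11 fell (19 and 11 adjusted over the list alone, 8 and 4 by at least 1 log2 unit; camera adjusted p = 0.200). SPP1, the gene of the CD44 ligand osteopontin, rose by 6.28 and EGFR by 2.89, while the ankyrin gene ANK3 (-2.79) and the Src family kinase gene FYN (-2.06) fell. Among integrins, 9 of the 19 measured rose and 8 fell (10 and 8 adjusted over the list alone, 5 and 4 by at least 1 log2 unit; camera adjusted p = 0.746). The subunit genes ITGA3 (4.88) and ITGB4 (1.94) rose and ITGB8 (-2.25) fell. ITGA8 fell by 3.15 on its representative probe set, with 3 of its 4 probe sets lower and 1 higher.

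Matrix genes split likewise. Among extracellular matrix proteins, 13 of the 38 measured rose and 14 fell (13 and 16 adjusted over the list alone, 5 and 7 by at least 1 log2 unit; camera adjusted p = 0.640). Besides THBS1, the collagen gene COL13A1 rose by 4.06, and tenascin C (TNC, -5.15) and the laminin gene LAMA4 (-4.80) fell. Past the threshold, 1 of 3 probe sets of TNC and 3 of 5 of LAMA4 fell and 0 rose. The median of this list was 0.056 and its mean -0.045, and camera placed it lower, so that median and test differed in sign. Of matrix proteases and inhibitors, 15 of the 32 measured rose and 9 fell (16 and 10 adjusted over the list alone, 9 and 4 by at least 1 log2 unit; camera adjusted p = 0.176). The protease genes ADAMTS6 (5.16) and PLAU (5.13), the latter encoding urokinase, rose, and ADAMTS5 (-4.27) and ADAM23 (-1.95) fell. In the list of proteoglycans and heparan sulfate enzymes, 13 of the 32 measured rose and 12 fell (13 and 12 adjusted over the list alone, 10 and 10 by at least 1 log2 unit; camera adjusted p = 0.699). With SRGN, the heparan sulfate polymerase gene EXT1 rose by 2.74, and the sulfotransferase genes HS6ST2 (-6.41) and HS3ST3B1 (-5.21) fell.

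Markers of epithelial and mesenchymal cells gave no single direction. Of epithelial genes, 12 of the 31 measured rose and 12 fell (13 and 12 adjusted over the list alone, 5 and 11 by at least 1 log2 unit; camera adjusted p = 0.559). The adhesion molecule gene EPCAM (-6.18) and the protease inhibitor gene SPINT2 (-5.82) fell, while the keratin gene KRT18 rose by 2.84 and the claudin gene CLDN7 by 2.74. The median was 0.10 against a mean of -0.61. Of mesenchymal genes, 18 of the 31 measured rose and 9 fell (18 and 9 adjusted over the list alone, 12 and 6 by at least 1 log2 unit), and camera gave adjusted p = 0.0649. Without native replicate 1 this was 0.0495 and without native replicate 3 it was 0.0498. Besides AXL, the BMP antagonist gene GREM1 rose by 5.83, and TCF4 (-3.49) and IGFBP5 (-3.42) fell. Among cadherins and protocadherins, 12 of the 32 measured rose and 13 fell (12 and 13 adjusted over the list alone, 3 and 12 by at least 1 log2 unit; camera adjusted p = 0.592, median 0.088, mean -0.44). CDH18 (4.91) and PCDHB5 (4.59) rose, and FAT3 (-4.63) and PCDH7 (-4.51) fell.

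Kidney, neuronal and pluripotency lists were not called. In the kidney lineage list, 8 of the 26 measured rose and 9 fell (8 and 9 adjusted over the list alone, 1 and 7 by at least 1 log2 unit; camera adjusted p = 0.490, median 0.047, mean -0.52). The nephron progenitor transcription factor gene SALL1 (-5.06) and the transcription factor gene EMX2 (-3.52) fell, and FOXD1 (1.68) and the podocalyxin gene PODXL (0.60) rose. Of neuronal genes, 7 of the 32 measured rose and 10 fell (7 and 10 adjusted over the list alone, 1 and 10 by at least 1 log2 unit; camera adjusted p = 0.208, median 0.027, mean -0.94). The neurofilament gene NEFL (-6.91) and the RNA-binding protein gene ELAVL2 (-6.43) fell, whereas the adhesion molecule gene L1CAM rose by 6.54 and the enolase gene ENO2 by 0.55. In the pluripotency and germline list, 11 of the 23 measured rose and 4 fell (11 and 4 adjusted over the list alone, 4 and 4 by at least 1 log2 unit; camera adjusted p = 0.265). LIN28B and PROM1 (-3.57) fell, and the cancer-testis antigen genes PRAME (17.7-fold) and MAGEA1 (6.48-fold) rose.

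Wnt, Notch and YAP/TAZ, cyclin and cell cycle lists were not called. For the Wnt pathway, 10 of the 32 measured rose and 15 fell (10 and 15 adjusted over the list alone, 5 and 14 by at least 1 log2 unit; camera adjusted p = 0.208), with rises of the secreted antagonist genes DKK1 (6.86) and SFRP1 (5.17) and falls of the transcription factor gene LEF1 (-5.20) and APCDD1 (-4.48). Among Notch and YAP/TAZ targets, 14 of the 28 measured rose and 13 fell (14 and 13 adjusted over the list alone, 10 and 9 by at least 1 log2 unit; camera adjusted p = 0.905). The YAP targets AXL and ANKRD1 (4.31) rose and the Notch targets HES1 (-5.45) and HEY1 (-5.00) fell. Of cyclins D and CDK inhibitors, 5 of the 15 measured rose and 7 fell (5 and 7 adjusted over the list alone, 2 and 4 by at least 1 log2 unit; camera adjusted p = 0.329). CCND1 rose by 3.13 and the CDK inhibitor gene CDKN1A by 1.25, while CCND2 (-6.53) and the CDK inhibitor gene CDKN2A (-5.86) fell, the latter with 2 probe sets lower and 1 higher. In cell cycle and mitosis, 9 of the 38 measured rose and 19 fell (9 and 20 adjusted over the list alone, 1 and 6 by at least 1 log2 unit; camera adjusted p = 0.0556, and 0.0492 without native replicate 2). The kinetochore kinase gene TTK (-1.27) and CCNE1 (-1.52) fell and the centromere histone gene CENPA (1.03) and CDC20 (0.83) rose.

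Among p53 targets, 13 of the 25 measured rose and 7 fell (13 and 7 adjusted over the list alone, 6 and 3 by at least 1 log2 unit; camera adjusted p = 0.265). The cytokine gene GDF15 rose by 5.28 and the kinase gene PLK2 by 4.39, and the BH3-only gene PMAIP1 (-4.94) and SESN1 (-2.08) fell. Of apoptosis regulators, 15 of the 30 measured rose and 12 fell (15 and 12 adjusted over the list alone, 5 and 3 by at least 1 log2 unit; camera adjusted p = 0.699). CASP4 (4.08) and BOK (3.51) rose, and the pro-apoptotic gene BCL2L11 (-4.21) fell. The anti-apoptotic gene BCL2 fell by 2.14 on its representative probe set, with 2 of its probe sets higher and 1 lower. In the list of ABC transporters, 6 of the 22 measured rose and 11 fell (6 and 11 adjusted over the list alone, 4 and 1 by at least 1 log2 unit, camera adjusted p = 0.265). ABCB1 (-4.34), which encodes P-glycoprotein, and ABCD4 (-0.98) fell, while ABCC2 (2.41) and ABCA1 (1.54) rose.

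In cholesterol biosynthesis, 10 of the 19 measured rose and 3 fell (10 and 3 adjusted over the list alone, 2 and 2 by at least 1 log2 unit; camera adjusted p = 0.0714). FDPS (1.29) and PMVK (1.24) rose and SC5D (-1.33) and TM7SF2 (-1.16) fell, all of them enzymes of the pathway. Of unfolded protein and amino acid stress genes, 17 of the 33 measured rose and 8 fell (18 and 8 adjusted over the list alone, 5 and 2 by at least 1 log2 unit; camera adjusted p = 0.234). Next to the fall of PSAT1, VLDLR (-1.35) fell and the amino acid transporter gene SLC7A5 (1.94) rose. The phosphatase gene PSPH rose by 1.63 on its representative probe set but had 1 probe set higher and 1 lower, and the mean of its probe sets (0.12) did not pass the threshold. Among ribosomal proteins, 3 of the 29 measured rose and 9 fell (3 and 7 adjusted over the list alone, 0 and 0 by at least 1 log2 unit; camera adjusted p = 0.208). RPL30 (0.39) and RPL3 (0.35) rose and RPS15 (-0.46) and RPL35 (-0.42) fell.

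Lists of markers of other cell types were read for signs of other cells. Dim probe sets as a whole lay slightly higher in the CD44s cells, by a median of 0.0973 in the dimmest 25% of probe sets and 0.14 in the next 25%, so the counts of changes of at least 1 log2 unit stand beside those of all calls. Of leukocyte markers, 11 of the 20 measured rose and 1 fell (12 and 1 adjusted over the list alone, 1 and 1 by at least 1 log2 unit; camera adjusted p = 0.0729). The monocyte marker CD14 (1.51) and the integrin gene ITGB2 (0.79) rose and the actin-bundling gene LCP1 (-3.63) fell. Of fibroblast and endothelial markers, 7 of the 19 measured rose and 2 fell (7 and 2 adjusted over the list alone, 2 and 0 by at least 1 log2 unit; camera adjusted p = 0.274). The surface glycoprotein gene THY1 rose by 3.90, from 6.18 ± 0.285 to 10.08 ± 0.231 (SD, n = 3), and the endothelial kinase gene TIE1 by 1.05 within the dim range. The matrix genes LUM (-0.81) and POSTN (-0.78) fell within that range, and the mean of the POSTN probe sets (-0.15) did not pass. Of markers of carcinoma and hepatocyte lines, 5 of the 20 measured rose and 0 fell (3 and 0 adjusted over the list alone, 3 and 0 by at least 1 log2 unit; camera adjusted p = 0.102). SFN, encoding the protein stratifin, rose by 4.07, from 9.02 ± 0.101 to 13.09 ± 0.0356 (SD, n = 3), and AFP, encoding alpha-fetoprotein, by 1.29 to 5.88.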

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

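Control probe sets for bacterial and phage sequences, which hold no human gene and enter no comparison, shifted between the groups, and the test below was chosen after this was seen. All 8 dim ones (mean under the median of all probe sets) lay higher on the CD44s arrays, by 0.042 to 0.324 and by a median of 0.136 log2 units. Of the 37 brighter ones, 29 with means of 5.75 to 10.65 were higher too, by 0.034 to 0.454, and 8 with means of 11.38 to 14.54 were lower, by -0.264 to -0.058, with a median of 0.156 over all 37. A rise was thus not limited to the dim controls. The 8 dim ones carry only the names Lys and Trpn, and the 8 lower ones only BioD and Cre. Probe sets of the same control are not independent, so these counts overstate how many controls moved. Human probe sets had a median difference of 0.0973 in the dimmest 25%, where 75.8% of calls were higher, and of -0.0808 in the brightest 25%, where 43.6% were. After cyclic loess the dimmest 25% held 550 higher and 808 lower calls, against 1530 and 488 as deposited. An offset of the deposited values at low intensity, a trend over the whole range of brightness, differing amounts of added controls and a true rise of dim genes stay open for the small rises, and no biological explanation was tested.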

How the results depend on the processing

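Counts of changed probe sets and genes stayed within 1.5 times the main count in every alternative except 1: at an adjusted p under 0.01, 8650 probe sets were higher, against 13314, as fewer pass a stricter threshold. Leaving out 1 array gave 21508 to 23793 changed probe sets, 9941 to 10796 changed genes and 8 to 9 called lists. Deviations of same-numbered arrays from their group means correlated at -0.0107, 0.0729 and 0.0383, and those of differently numbered arrays at -0.0936 to 0.0738. Deviations from a group mean depend on each other, so a pairing by replicate number was neither shown nor excluded. A fit with the replicate block called 24926 probe sets and 11132 genes. Of 8 gene lists called by camera, 0 were called with an estimated correlation, and fry called 30 of the 33 lists. Directions that turned were those of extracellular matrix proteins with the mean of all probe sets per gene (mean log2 difference 0.18), and with fry those of extracellular matrix proteins (-0.0447), proteoglycans (-0.30), the Wnt pathway (-0.30) and pluripotency genes (0.0011), where the values themselves did not move and the test weights genes otherwise. The cause of the first was not tested. Lists that gained a camera call after cyclic loess, which was added after seeing the data, were mesenchymal genes (0.0453), cholesterol biosynthesis (0.0149) and the unfolded protein response (0.0453). Mesenchymal genes also gained it without native replicate 1 (0.0495) and without native replicate 3 (0.0498). Cholesterol biosynthesis gained it with the mean of all probe sets per gene (0.00869), and cell cycle genes with array weights (0.0478) and without native replicate 2 (0.0492). Of 2013 values of named genes under alternatives, 2011 kept direction and call, and PSPH and POSTN lost the call with the mean of all probe sets per gene. Most named genes were picked for passing the threshold with the largest changes on these same arrays, so this says little about other genes. Of the 3604 genes changed by at least 1 log2 unit, 72.2% were shared with that setting and at least 95.1% with each of the other 13 settings compared, which did not include the unmoderated test or the stricter threshold. Signal over background is not known here, so which dim levels lie above it was not settled.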

Other observations

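Gene families were picked by symbol after the main results, which had shown some of their members, such as S100A6, and 18 were tested with camera. Of S100 calcium-binding protein genes, 13 of 19 rose and 0 fell (adjusted p = 5.95e-05, and adjusted p = 0.0778 with an estimated correlation), with rises of 5.56 for S100A16, 4.44 for S100A3 and 2.93 for S100A2 beside that of S100A6. Caveolin and cavin genes, which encode the coat of caveolae, rose in 5 of 7 cases and fell in 1 (adjusted p = 0.0143, and adjusted p = 0.173 with an estimated correlation). CAVIN2 rose by 6.78, CAVIN3 by 5.31, CAVIN1 by 3.47 and CAV1 by 2.73. Among serpins, 12 of 30 rose and 1 fell (adjusted p = 0.0311, and adjusted p = 0.296 with an estimated correlation), led by SERPINB7 (4.53).

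Genes of the HOXD cluster, which set position along the body axis, were lower: 0 of 8 rose and 7 fell (adjusted p = 5.95e-05, and adjusted p = 0.173 with an estimated correlation). HOXD10 (-5.58) and HOXD11 (-4.22) fell. Of ZNF zinc finger genes, 72 of 466 rose and 240 fell (adjusted p = 5.22e-06, and adjusted p = 0.0778 with an estimated correlation), with a median of -0.34. ZNF91 (-4.88) and ZNF711 (-4.83) fell and ZNF804A (4.47) and ZNF185 (4.43) rose. Of Eph receptors and ephrins, 4 of 21 rose and 11 fell (adjusted p = 0.0464, and adjusted p = 0.389 with an estimated correlation), with EPHA7 at -7.06 and EPHA2 at 2.92. In a rerun chosen after these results, the median of each of these 6 families kept its sign after quantile normalization, centring and cyclic loess, and 4 of the families kept their camera calls. The call of Eph receptors and ephrins ended in all 3 (adjusted p = 0.0945, 0.0515 and 0.0606), and that of serpins after quantile normalization (0.0945) and cyclic loess (0.101). After cyclic loess 8 serpins, 9 S100 genes and 2 genes of Eph receptors and ephrins were higher, against 12, 13 and 4 as deposited. The other 12 families were not called on the deposited values. In a region around 9p21, chosen after the values were seen, 17 of 40 genes were lower on the CD44s arrays, 2 were higher and 21 did not pass the threshold. All of those 21 except PLAA (means of 9.54 and 9.39) were dim in both groups, many of them interferon genes. Of the 2 higher genes PLIN2 rose by 1.89, and IFNB1 rose by 0.40 within the dim range. The largest falls there were those of ELAVL2 (-6.43), CDKN2A (-5.86), CDKN2B (-5.71) and MTAP (-2.91), and their cause was not tested.

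In the tests that follow, those on normalization, on another cell line, on transcripts of the transfected sequence and on genes moving against their chromosome were chosen after the result was seen. The breadth of the difference was weighed first. Other splits of the 6 arrays are too few for a share under 0.05, as only 10 exist: 1 of them, the real one, called 25175 probe sets and 11302 genes, and the highest of the others called 0 and 0 (limma, 1080 probe sets at an unadjusted p under 0.05). A difference in RNA integrity of the size set in advance, 1 log2 unit in the 3' to 5' ratio, was not there, since GAPDH differed by -0.0334 and ACTB by -0.48, the latter with no overlap of the arrays. Normalizing the deposited values again changed the count little. Under quantile, centred and cyclic loess values the number of genes changed by at least 1 log2 unit was 98.9% to 101.1% of the main number. The deposited values had already been processed in a way not given here, and that processing could not be tested by a further step. Beside that processing, the clone itself, the transfection and another cell line under one of the labels stay open. So does a batch or handling difference between the groups, as scan dates and batches are not given. Each of these may part the groups in this way. The group means correlated at r = 0.802 across 13085 genes above the median, which are not independent replicates. This value lies between the bounds chosen for another cell line, but no known pair of different lines was compared here to anchor those bounds. It therefore does not tell whether another cell line lies under a label, and these explanations cannot be told apart. For CD44, the probe set based on the template rose by 5.92, which is -0.159 relative to the highest of the other CD44 probe sets, and with probe positions not used here transcripts of the transfected sequence and of the cells' own gene cannot be told apart.

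Expression also shifted by chromosome. Relative to all 13057 genes above the median of the array, the median log2 difference was -0.84 for chromosome 18, -0.56 for chromosome 9 and -0.44 for chromosome 6, against 0.30 for chromosome 8 and 0.24 for chromosome 14. The largest, 0.844 in size, was reached in 0 of 1000 shuffles of genes over chromosomes, whose 95th percentile was 0.167. Of 23 chromosomes, 15 passed (permutation test, adjusted p = 0.00191 for those named, adjusted from the smallest p that the shuffles can give). The shuffles moved single genes and so treat neighbouring genes as independent. Where neighbours move together, the p-values are too low and the count of 15 may be too high. Copy number differences of whole chromosomes between the CD44s clone and the native cells are a candidate explanation for these shifts, as a hypothesis. Among those 13057 genes 3362 changed by at least 1 log2 unit, and of the 2346 on the chromosomes that passed 31.2% moved against their chromosome's median. For these genes, a direct effect of the copy number of their own whole chromosome is argued against as the whole cause. Of the 3362, 87.2% stayed past 1 log2 unit after each chromosome's median was subtracted. That share lies between the bounds set in advance, so the test set in advance does not decide. The share moving against their chromosome was a later choice, and it includes chromosomes with small medians, such as chromosome 1 (0.0891). Effects of copy number on genes of other chromosomes and copy number differences of smaller parts were not tested.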
